A study of Mus musculus with 24 samples.

How the data were processed

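RNA from mouse embryonic fibroblasts was measured on 24 one-colour Agilent arrays, 1 sample per array, with Cy3-labelled material made from total RNA, per the labels' protocols. The labels put the arrays into 10 groups, 2 groups of 4 wild-type arrays and 8 groups of 2 arrays. Each array was taken as 1 replicate. The labels do not say that replicates came from separate cultures.

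Spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, per the file headers and the submitters' processing notes. The deposited scanner files give for each spot a processed signal, which is a linear intensity after background subtraction and spatial detrending, per the file headers. They also give the median intensity of the spot and of its local background without any correction, per the file headers. Deposited flags, coded as 0 or 1, mark spots that the software found well above background, saturated or non-uniform. No normalization between arrays had been applied to these intensity values. The authors' deposited table of processed values held log2 values of the same arrays. Set against the scanner values, 99.3% of the probe values, taken as deviations from each probe's median, differed by at most 0.001 from the log2 processed signal shifted by each array's 75th percentile. The deposited log2 values were thus centred per probe, and the baseline used for that centring stayed unknown. Column medians of the deposited log2 values, untreated then treated, were -0.13, 0.12, -0.21, -0.22, -0.02, 0.07, -0.12 and -0.24 for wild type. They were -0.19, 0.31, 0.39 and -0.32 for Perk-null and -0.19, -0.25, 0.49 and -0.06 for Atf4-null arrays. For Fv2E-PERK they were -0.23, -0.18, -0.19 and -0.08, and for eIF2α A/A -0.01, 0.03, 0.04 and -0.02.

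Control spots were left out. Spots of 1 probe were averaged without those flagged as outliers, and a probe with only such spots kept them. No spot was saturated. The values tested were log2 of the processed signal minus the array's 75th percentile of it, over 55681 probes. That percentile ranged from 111 to 418 intensity units, and 45.1% to 58.2% of probes were well above background.

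Probes were named through the accession in the scanner files, looked up without version in a RefSeq table of mouse assembly GRCm38.p6, which served for names only. Of the probes, 26631 matched 1 gene symbol and 29050 matched none. The matched probes covered 20170 genes. Arrays of different scan runs carried different versions of the array design, so 49 probes were named from the earlier version, and 57 probes had different genes in both versions. Each gene was represented by its brightest probe, which mattered for 4563 tested genes with more than 1 probe. The probes of Eif2s1 did not follow each other between scan runs. A gene was tested if its probe was well above background on every array of at least 1 group. That left 14458 genes and put aside 5712.

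The arrays came from 3 scan runs and 6 slides. Run 1 held wild-type replicates 1 and 2 and the Atf4-null arrays, with all treated arrays on 1 slide and all untreated arrays on another. Run 2 held wild-type replicates 3 and 4 and the Perk-null arrays, and run 3 held the Fv2E-PERK and eIF2α A/A arrays. Slide and treatment cannot be told apart within run 1, since each of its slides held only 1 treatment. Run 3 shares no group with the other runs, so untreated eIF2α A/A and Fv2E-PERK cells were not set against untreated wild-type cells.

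Differences were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0), two-sided. A single model held all 24 arrays, with 10 group means and a fixed term for run 2, and left 13 residual degrees of freedom plus 2.23 prior ones. The Benjamini-Hochberg adjustment was applied within each of the 10 contrasts, and a gene was called at an adjusted p under 0.05. The contrasts were the response to tunicamycin in wild-type, Perk-null, Atf4-null and eIF2α A/A cells, the response to AP in Fv2E-PERK cells, the difference of each mutant response from the wild-type response, and the difference of untreated Perk-null and Atf4-null from untreated wild-type cells. A further set held genes higher with tunicamycin in wild-type cells whose response was smaller in all 3 mutants. A response counted as smaller also when it was reversed. An adjusted p given for a gene is limma's.

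Gene lists were tested with camera of limma at a preset correlation of 0.01, and the Benjamini-Hochberg adjustment ran over the 26 lists of a contrast. The same test with a correlation estimated from the residuals and the rotation test fry were run beside it. fry tests whether a list's genes move one way on balance and sets the list against no other genes. Of the lists, 19 were functional and 7 held markers. The functional lists were stress transcription factors and integrated stress response (ISR) signalling, amino acid and one-carbon synthesis, amino acid transporters, cytosolic aminoacyl-tRNA synthetases, ER chaperones and folding enzymes, ER-associated degradation, ER translocation and secretory traffic, cholesterol synthesis and uptake, cell cycle and DNA replication, the NRF2 oxidative stress response, extracellular matrix, autophagy, apoptosis regulators, p53 targets, interferon-stimulated genes, inflammatory cytokines and chemokines, mitochondrial proteases and chaperones, cytosolic heat shock proteins, and glycolysis and hypoxia targets. Marker lists covered fibroblasts, epithelial, endothelial, haematopoietic, muscle and neural cells, and adipocytes with bone or cartilage cells. In no list test that passed did the median, the mean and the direction of the test differ in sign.

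The grouping, the contrasts, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the targeted genes Eif2ak3, Atf4 and Eif2s1, up to 8 of the largest rises and 6 of the largest falls of a contrast, up to 2 rises and 2 falls of each list or its lowest-p member, 9 known ER stress genes, and the 20 genes of the 3-mutant set with the largest wild-type rise. Genes taken for size had to be called, well above background on all arrays of the higher group, and without overlap between the groups' arrays (for a difference of responses, between the changes within replicate numbers; for untreated cells, within the shared run), and predicted or clone-named genes were left out. Among these, genes whose call held without any 1 array were preferred as examples, a preference set after the values were seen.

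Replicate numbers were checked for pairing from the correlation, across genes, of deviations from the group means. Same-numbered untreated and treated wild-type arrays gave r of 0.502, 0.365, 0.573 and 0.608. Pairs with different numbers within a run gave 0.508, 0.343, 0.578 and 0.592, so the pairing came from the scan run or from what goes with it. The model held this as a term for the level of a run, not for a difference of response between runs. Sex-linked genes differed between the wild-type arrays of runs 1 and 2, so that term covered the origin of the wild-type cells as well as the scan. Values with the replicate number as a block stand beside a result where they changed it.

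The alternatives tried were quantile normalization, normexp (offset 50) on the median spot and background intensity followed by quantile normalization, the deposited log2 values, no filter on dim probes, only genes well above background on all 24 arrays, the mean of a gene's probes, no run term, scan day or slide as a random block, wild-type arrays of 1 run only, a replicate block, only the arrays of the groups compared, eBayes with trend and robust settings, an adjusted p under 0.01, a change of at least 2-fold, and each array left out in turn. Another 4 were chosen after seeing the data, namely a fixed term for slide 3, a replicate block with the Perk-null numbers crossed, array weights estimated per run, and Fisher tests of the 3-mutant set against the genes raised in wild type. The mean spot intensity planned for normexp was not among the columns used, and the median took its place.

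The procedure was tested on simulated data for the 14458 genes with 200 changed, without Atf4-null, eIF2α A/A or AP contrasts. The shares below describe these data only. On the arrays more genes were called and the spread differed by run. For the wild-type response, 21%, 68% and 95% of the changed genes were recovered at 1.5-fold, 2-fold and 4-fold, and false calls made up 4.55%, 5.56% and 6.40% of the calls. The Perk-null response recovered 0%, 46.5% and 78% of them, and the difference between the Perk-null and wild-type responses 0%, 27.5% and 77.5%. For untreated Perk-null against wild-type cells the recovery was 3%, 51.5% and 88.5%, with 11.9% false calls at 4-fold. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.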

Results

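Gene expression was measured in mouse embryonic fibroblasts, cultures grown from embryos in serum-containing medium, of 5 genotypes. Wild-type cells were compared with cells lacking PERK, a kinase of the endoplasmic reticulum (ER) that phosphorylates the translation factor eIF2α when proteins misfold. Other cells lacked ATF4, the transcription factor whose translation rises when eIF2α is phosphorylated. Homozygous eIF2α A/A cells carry alanine in place of the phosphorylated serine. Each of these 4 genotypes was left untreated or given tunicamycin at 2 µg per mL for 12 h by its label, while the shared protocol names 12 or 24 h. The data file of untreated Perk-null replicate 2 is named for a 24 h mock treatment, unlike its label. Tunicamycin blocks N-glycosylation and so causes misfolded proteins to gather in the ER. Cells with Fv2E-PERK, a fusion of the PERK kinase domain that a dimerizing compound can switch on without ER stress, were left untreated or given AP for 12 h. The labels name this compound only by that abbreviation and give no dose.

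Wild-type groups had 4 arrays each and the other 8 groups 2 each, and 14458 genes were tested. The arrays' number limits the precision. The p-values measure only the spread between these samples, which may be technical. That spread differed between the scan runs. The median SD per gene was 0.209 to 0.314 (log2) in the groups of run 1 and 0.0573 to 0.15 in those of runs 2 and 3. Levels below are log2 signal over the array's 75th percentile, as mean ± SD, and changes are log2 differences ± SE.

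The wild-type arrays of the 2 runs differed in sex-linked genes, which were chosen after their values were seen. Xist, the RNA that silences 1 of the X chromosomes in female cells, read 1.65 to 2.11 on the 4 wild-type arrays of run 1. On the 4 of run 2 it was not well above background. The Y-linked genes Ddx3y and Eif2s3y read 1.72 to 1.95 and 2.52 to 2.88 on the wild-type arrays of run 2 and were not well above background on those of run 1. Xist was well above background and both Y-linked genes were not on all Perk-null, Atf4-null and eIF2α A/A arrays, and the reverse held for Fv2E-PERK. The names of the data files also set them apart, as the wild type of the Atf4 line in run 1 and of the Perk line in run 2, where the labels give 1 wild type. The wild-type cells of the 2 runs were thus not of 1 origin, and scan run and cell origin cannot be told apart. Values by run below cover both.

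The targeted genes were read first in every group. Atf4 lay at 7.41 ± 0.24 in untreated and 8.88 ± 0.26 in tunicamycin-treated wild-type cells (n = 4 each). On the Atf4-null arrays it read 2.79 and -0.05 without and -4.27 and 0.01 with tunicamycin, and on the array with the lowest value it was not well above background. Untreated Atf4-null and wild-type cells differed by -5.83 ± 0.88 (limma, adjusted p = 0.000203). Eif2ak3, which encodes PERK, read 0.67 ± 0.49 in untreated wild-type (n = 4) and -0.24 ± 0.33 in untreated Perk-null cells (n = 2), with a difference in the fit with the run term of -1.20 ± 0.24 (adjusted p = 0.00102). Its probe may lie outside the deleted part of the gene and then checks nothing. In wild-type cells tunicamycin raised Eif2ak3 by 0.77 ± 0.18 (adjusted p = 0.0039) and Eif2s1, the gene of eIF2α, by 0.50 ± 0.14 (adjusted p = 0.0102). A second, dimmer Eif2s1 probe read 0.99 ± 1.48 untreated and 1.03 ± 1.35 treated (n = 4 each), without such a rise. The wild-type Atf4 change of 1.47 ± 0.66 did not pass the test (adjusted p = 0.0956), although all 4 treated arrays lay above all 4 untreated ones. The pooled spread of Atf4 included the 4 Atf4-null arrays. Nor did the Atf4 change pass in Perk-null (1.24 ± 0.94), eIF2α A/A (-0.06 ± 0.94) or Fv2E-PERK cells (0.81 ± 0.94), with adjusted p of 0.713, 0.99 and 0.757.

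**Figure D1:**
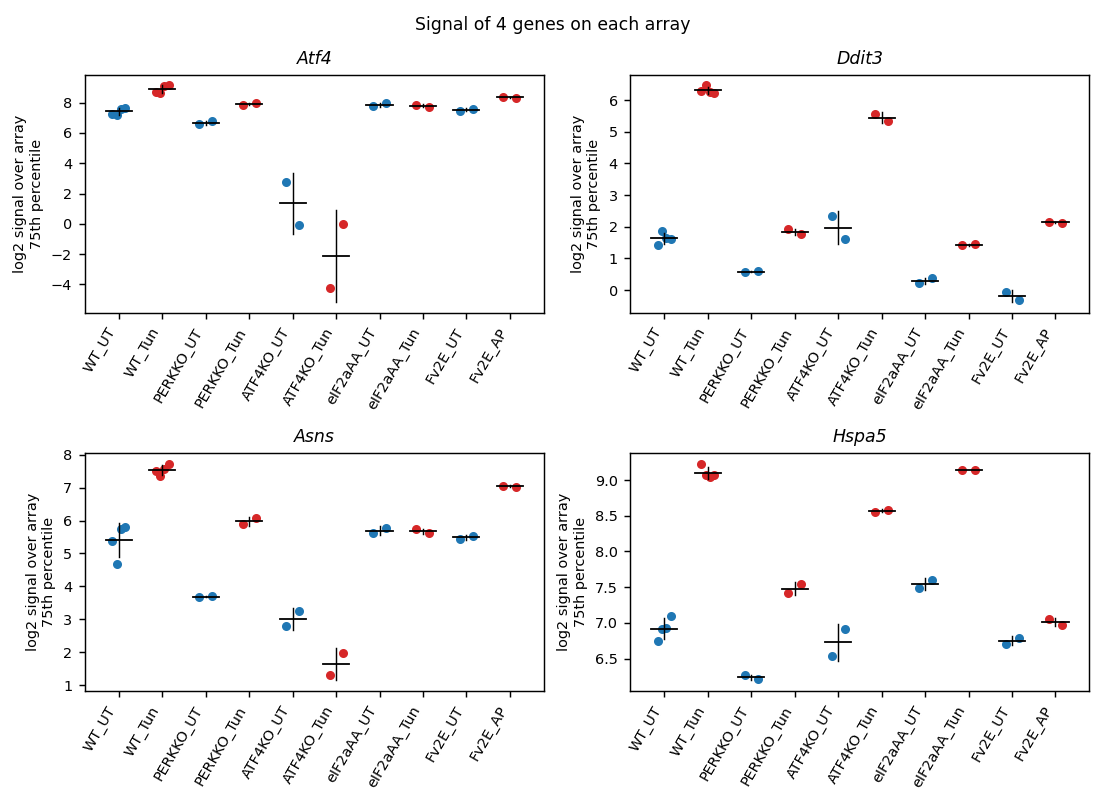
Log2 signal over the array's 75th percentile of Atf4, Ddit3, Asns and Hspa5 on each of the 24 arrays by group, with points for arrays and bars for the group mean ± SD. Atf4 lies at or below 2.79 on every Atf4-null array, and Hspa5 lies between 9.05 and 9.23 on the 4 treated wild-type arrays.

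The first question was which genes respond to ER stress in wild-type cells. Tunicamycin raised Ddit3, which encodes the pro-apoptotic factor CHOP, 25.5-fold (4.67 ± 0.14, n = 4 per group). Herpud1, a component of ER-associated degradation, rose 16.3-fold (4.03 ± 0.11). Hspa5, the ER chaperone BiP, rose by 2.18 ± 0.10, its co-chaperone Dnajb9 by 3.37 ± 0.10 and Xbp1, the transcription factor whose RNA is spliced by IRE1, by 1.81 ± 0.11. The largest rises were those of Car6, a secreted carbonic anhydrase (362-fold), Derl3, an ER membrane protein of the degradation pathway (7.81 ± 0.27), and Acox2, a peroxisomal acyl-CoA oxidase (7.43 ± 0.44). Akr1b7, an aldo-keto reductase gene, rose at least 21.9-fold. Such bounds set the brighter group's mean over the dimmer group's mean of, on each array, the higher of the lowest signal well above background and the gene's own signal. Among the largest falls were those of the stromelysin Mmp3 (-5.40 ± 0.86) and the neutrophil chemokines Cxcl5 (-4.75 ± 0.53) and Cxcl1 (-4.72 ± 0.67).

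Genes of the secretory pathway rose together. ER chaperones and folding enzymes had 26 higher and 0 lower of 26 (the same adjusted over the list alone), median 1.84 (adjusted p = 9.98e-25), counts being out of the list's tested members. Among them Sdf2l1 rose by 4.58 ± 0.14 and Hyou1 by 3.57 ± 0.12. ER-associated degradation had 18 higher and 1 lower of 24 (the same adjusted over the list alone), median 0.90 (adjusted p = 2.9e-11). Translocation and secretory traffic had 23 higher and 0 lower of 32 (23 and 1 adjusted over the list alone), median 0.62 (adjusted p = 7.42e-09). Within runs 1 and 2 the medians were 1.68 and 1.95 for chaperones, 0.80 and 0.87 for degradation and 0.62 and 0.67 for translocation.

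A second block was stress signalling and amino acid supply. The list of stress transcription factors and ISR signalling had 20 higher and 1 lower of 25 (21 and 1 adjusted over the list alone), median 1.93 (adjusted p = 3.21e-13). It included the pseudokinase gene Trib3 (3.56 ± 0.20), the secreted hormone Fgf21 (5.48 ± 0.49), Atf3 (3.45 ± 0.29) and the glutathione-degrading enzyme Chac1 (3.84 ± 0.29). Amino acid and one-carbon synthesis had 16 higher and 0 lower of 19 (17 and 0 adjusted over the list alone), median 1.78 (adjusted p = 2.08e-11). Asparagine synthetase Asns rose by 2.13 ± 0.17 and cystathionine gamma-lyase Cth by 4.01 ± 0.23. Amino acid transporters had 10 higher and 0 lower of 16 (the same adjusted over the list alone), median 1.49 (adjusted p = 4.7e-06), led by the cystine transporter Slc7a11 (4.65 ± 0.40) and the glycine transporter Slc6a9 (4.16 ± 0.23). The cytosolic aminoacyl-tRNA synthetases, among them Wars (2.60 ± 0.13), had 19 higher and 0 lower of 20 (20 and 0 adjusted over the list alone), median 1.20 (adjusted p = 2.9e-11, adjusted p = 0.0624 with an estimated correlation). Medians within runs 1 and 2 were 1.69 and 1.91 for ISR signalling, 1.70 and 1.65 for synthesis, 1.61 and 1.36 for transporters and 1.18 and 1.15 for the synthetases. With an estimated correlation the calls of the 3 secretory lists, ISR signalling, synthesis and transporters held, and those of no other list of the wild-type response did.

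Other lists moved downwards with both runs in the fit. Interferon-stimulated genes had 0 higher and 15 lower of 23 (0 and 16 adjusted over the list alone), median -1.52 (adjusted p = 9.78e-06, adjusted p = 0.423 with an estimated correlation). Their median was -2.89 in run 1 and -0.37 in run 2, where the shift did not pass (adjusted p = 0.327). Inflammatory cytokines and chemokines had 1 higher and 11 lower of 16 (the same adjusted over the list alone), median -2.15 (adjusted p = 9.87e-05, adjusted p = 0.341 with an estimated correlation), and medians of -3.24 and -0.75 in runs 1 and 2. Extracellular matrix genes had 1 higher and 18 lower of 30 (1 and 21 adjusted over the list alone), median -0.96 (adjusted p = 8.8e-08, adjusted p = 0.276 with an estimated correlation), and run medians of -1.50 and -0.35. Cholesterol synthesis and uptake, with Hsd17b7 at -1.51 ± 0.23, had 0 higher and 8 lower of 24 (the same adjusted over the list alone), median -0.48 (adjusted p = 0.00301, adjusted p = 0.538 with an estimated correlation). Its median was 0.37 in run 1 (adjusted p = 0.303) and -1.29 in run 2 (adjusted p = 3.01e-14). Muscle markers had 0 higher and 5 lower of 8 (0 and 6 adjusted over the list alone), median -1 (adjusted p = 0.00424, adjusted p = 0.244 with an estimated correlation), and run medians of -1.60 and -0.36. Fibroblast markers, among them Fap (-3.01 ± 0.39) and Ddr2 (1.32 ± 0.12), had 3 higher and 8 lower of 14 (3 and 9 adjusted over the list alone), median -0.65 (adjusted p = 0.0155, adjusted p = 0.0728 with an estimated correlation), and run medians of -0.73 and -0.40. Cell cycle and DNA replication, with thymidine kinase Tk1 at -1.53 ± 0.12, had 4 higher and 14 lower of 29 (4 and 16 adjusted over the list alone), median -0.44 (adjusted p = 0.00405, adjusted p = 0.423 with an estimated correlation), and run medians of -0.41 and -0.40.

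Smaller shifts passed for 3 further lists in wild-type cells. Mitochondrial proteases and chaperones, with the protease Lonp1 at 1.80 ± 0.08, had 12 higher and 3 lower of 20 (the same adjusted over the list alone), median 0.53 (adjusted p = 0.00155, adjusted p = 0.423 with an estimated correlation). Autophagy genes, with Atg13 at 1.37 ± 0.11, had 12 higher and 1 lower of 25 (13 and 1 adjusted over the list alone), median 0.32 (adjusted p = 0.0319, adjusted p = 0.469 with an estimated correlation). Glycolysis and hypoxia targets had 3 higher and 8 lower of 25 (the same adjusted over the list alone), median -0.18 (adjusted p = 0.0334, adjusted p = 0.423 with an estimated correlation). In run 1 alone autophagy (median 0.29, adjusted p = 0.167) and glycolysis (median -0.07, adjusted p = 0.181) did not pass, and in run 2 their medians were 0.30 and -0.25. The NRF2 response did not pass, with 4 higher and 4 lower of 22 (the same adjusted over the list alone), median 0.13 (adjusted p = 0.76), though its member Hmox1, heme oxygenase, rose by 2.25 ± 0.13. Nor did apoptosis regulators, with 5 higher and 8 lower of 25 (the same adjusted over the list alone), median -0.21 (adjusted p = 0.283), p53 targets, with 6 higher and 3 lower of 21 (7 and 5 adjusted over the list alone), median 0.28 (adjusted p = 0.738), or heat shock proteins, with 1 higher and 3 lower of 18 (the same adjusted over the list alone), median 0.10 (adjusted p = 0.76). Epithelial, endothelial, haematopoietic and neural markers and those of adipocytes and bone did not pass either (adjusted p = 0.58, 0.913, 0.299, 0.76 and 0.35).

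In all, 5424 of the 14458 genes were called in the wild-type response, 3067 higher and 2357 lower, of which 1861 changed at least 2-fold, 790 higher and 1071 lower. Within run 1 alone 4697 genes were called, and within run 2 3760. Of these, 3844 and 3101 were among the 5424. The higher genes made up 56.5% of the calls, and 46.3% with quantile normalization.

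The next question was what remained of this response without PERK. In Perk-null cells the amino acid transporter subunit Slc3a2 rose 8.82-fold (3.14 ± 0.21), Chac1 by 2.93 ± 0.41, Slc6a9 by 2.90 ± 0.32 and the chemokine Cxcl10 by 2.98 ± 0.28 (n = 2 per group). All 9 known ER stress genes rose, among them Asns by 2.29 ± 0.25, Trib3 by 2.24 ± 0.29, Herpud1 by 2.05 ± 0.16 and Ddit3 by 1.27 ± 0.20. The call of Atf3 (1.71 ± 0.41) was lost without any 1 of the 4 arrays and with the replicate number as a block. ER chaperones had 17 higher and 0 lower of 26 (23 and 0 adjusted over the list alone), median 0.96 (adjusted p = 2.68e-33), and Dnajb9 rose by 1.94 ± 0.14. ER-associated degradation, with Selenos at 2.08 ± 0.14, had 9 higher and 0 lower of 24 (12 and 0 adjusted over the list alone), median 0.48 (adjusted p = 1.24e-12). Translocation had 12 higher and 0 lower of 32 (18 and 0 adjusted over the list alone), median 0.45 (adjusted p = 1.4e-17). Transporters had 5 higher and 0 lower of 16 (10 and 0 adjusted over the list alone), median 0.60 (adjusted p = 9.06e-11). ISR signalling had 9 higher and 0 lower of 25 (11 and 1 adjusted over the list alone), median 0.70 (adjusted p = 2.38e-08). These 5 calls held with an estimated correlation.

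The calls of 6 further lists did not hold so in Perk-null cells. Genes of amino acid synthesis had 5 higher and 0 lower of 19 (9 and 2 adjusted over the list alone), median 0.57 (adjusted p = 1.23e-05, adjusted p = 0.0807 with an estimated correlation). The tRNA synthetases had 3 higher and 0 lower of 20 (9 and 0 adjusted over the list alone), median 0.42 (adjusted p = 2.6e-05, adjusted p = 0.27 with an estimated correlation). Cytosolic heat shock proteins had 4 higher and 0 lower of 18 (8 and 0 adjusted over the list alone), median 0.49 (adjusted p = 2.79e-07, adjusted p = 0.0807 with an estimated correlation). Glycolysis and hypoxia targets had 0 higher and 2 lower of 25 (0 and 4 adjusted over the list alone), median -0.35 (adjusted p = 7.13e-08, adjusted p = 0.0538 with an estimated correlation). Cholesterol synthesis, with Acat2 at -0.79 ± 0.20, had 0 higher and 0 lower of 24 (0 and 1 adjusted over the list alone), median -0.62 (adjusted p = 5.28e-07, adjusted p = 0.412 with an estimated correlation). NRF2 genes had 1 higher and 0 lower of 22 (4 and 0 adjusted over the list alone), median 0.17 (adjusted p = 0.00465, adjusted p = 0.412 with an estimated correlation). In all 330 genes were called, 271 higher and 59 lower, and 153 with the replicate block. The count was 146 and 154 without untreated replicates 1 and 2, and 206 and 103 without treated replicates 1 and 2. With only the Perk-null arrays in the limma fit 0 genes were called, against 1969 at an unadjusted p under 0.05.

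Tested directly, the response of Perk-null cells differed from that of wild-type cells in 1903 genes, 943 with a higher and 960 with a lower change. The difference of log2 responses was -3.40 ± 0.24 for Ddit3 and -3.61 ± 0.40 for Cth. It was -3.65 ± 0.24 for Sdf2l1 and -2.58 ± 0.21 for Hyou1, both ER chaperones. Angptl4, a secreted lipase inhibitor (6.80 ± 0.84), and the chemokines Cxcl5 (6.29 ± 0.93) and Cxcl10 (4.14 ± 0.34) had higher changes. Of the genes raised in wild type, 889 of 3067 (29.0%) had a smaller and 5 a larger response in Perk-null cells. Of those lowered, 833 of 2357 (35.3%) had a smaller and 3 a larger one. Over the 790 genes that rose at least 2-fold in wild type the median Perk-null change was 0.164 of the wild-type change.

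ISR signalling responded less in Perk-null cells, with 1 higher and 12 lower of 25 (1 and 16 adjusted over the list alone), median -1.33 (adjusted p = 1.53e-08). So did chaperones, with 0 higher and 16 lower of 26 (1 and 18 adjusted over the list alone), median -0.83 (adjusted p = 7.92e-14), and ER-associated degradation, with 1 higher and 10 lower of 24 (1 and 12 adjusted over the list alone), median -0.42 (adjusted p = 2.17e-06). Fibroblast markers had 5 higher and 0 lower of 14 (8 and 1 adjusted over the list alone), median 1.20 (adjusted p = 0.00232). These 4 calls held with an estimated correlation. Translocation did not pass, with 1 higher and 3 lower of 32 (the same adjusted over the list alone), median -0.10 (adjusted p = 0.278). Transporters had 2 higher and 4 lower of 16 (2 and 8 adjusted over the list alone), median -0.71 (adjusted p = 0.0494, adjusted p = 0.288 with an estimated correlation). Amino acid synthesis had 0 higher and 11 lower of 19 (0 and 12 adjusted over the list alone), median -1.12 (adjusted p = 2.66e-07, adjusted p = 0.0506 with an estimated correlation). The tRNA synthetases had 0 higher and 6 lower of 20 (0 and 11 adjusted over the list alone), median -0.73 (adjusted p = 4.36e-07, adjusted p = 0.208 with an estimated correlation). Against wild-type runs 1 and 2 the medians were -1.01 and -1.06 for ISR signalling, -0.74 and -0.84 for chaperones and -1.21 and -1.03 for synthesis. Interferon-stimulated genes had 6 higher and 0 lower of 23 (8 and 0 adjusted over the list alone), median 2.04 (adjusted p = 1.93e-06, adjusted p = 0.397 with an estimated correlation), and medians of 3.78 and 0.42 against runs 1 and 2. Matrix genes had 7 higher and 0 lower of 30 (19 and 0 adjusted over the list alone), median 1.15 (adjusted p = 4.52e-08, adjusted p = 0.288 with an estimated correlation), and medians of 1.72 and 0.68. For cholesterol genes these medians were -0.75 and 0.83. Against runs 1 and 2 alone 2569 and 1846 genes differed, and 1177 with the replicate block. Without untreated replicates 1 and 2 of Perk-null cells the count was 981 and 1266, and without treated replicates 1 and 2 it was 1110 and 1113.

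Cells without ATF4 addressed which part of the response needs that factor. In these cells the chaperone Sdf2l1 rose by 4.77 ± 0.19, Herpud1 by 3.54 ± 0.16, Dnajb9 by 3.32 ± 0.14 and Ddit3 by 3.47 ± 0.20 (n = 2 per group). Asns (-1.38 ± 0.25) and the serine synthesis enzyme Psat1 (-2.36 ± 0.28) fell. Chac1 (-0.58 ± 0.41, adjusted p = 0.305) and Atf3 (-0.33 ± 0.41, adjusted p = 0.582) did not pass. Among the largest falls were isopentenyl isomerase Idi1 (-4.61 ± 0.59), the matrix protein gene Ccn2 (-4.78 ± 0.39) and the skeletal muscle myosin genes Myh1 (-5.58 ± 0.72) and Myh8 (-5.56 ± 0.78). Chaperones had 24 higher and 0 lower of 26 (the same adjusted over the list alone), median 1.64 (adjusted p = 8.91e-25). ER-associated degradation had 14 higher and 2 lower of 24 (15 and 2 adjusted over the list alone), median 0.67 (adjusted p = 5.32e-06). The cell cycle list, with the mitotic kinase Plk1 at -3.10 ± 0.36, had 0 higher and 23 lower of 29 (0 and 26 adjusted over the list alone), median -1.59 (adjusted p = 3.05e-15). With an estimated correlation the calls of these 3 lists held. Cholesterol synthesis and uptake had 0 higher and 23 lower of 24 (the same adjusted over the list alone), median -2.48 (adjusted p = 4.34e-13, adjusted p = 0.367 with an estimated correlation).

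ISR signalling did not pass in Atf4-null cells, with 7 higher and 4 lower of 25 (the same adjusted over the list alone), median 0.06 (adjusted p = 0.193). Amino acid synthesis had 0 higher and 7 lower of 19 (the same adjusted over the list alone), median -0.69 (adjusted p = 0.0053, adjusted p = 0.367 with an estimated correlation). Heat shock proteins had 0 higher and 10 lower of 18 (the same adjusted over the list alone), median -0.60 (adjusted p = 0.00163, adjusted p = 0.367 with an estimated correlation). The tRNA synthetases had 0 higher and 9 lower of 20 (1 and 10 adjusted over the list alone), median -0.43 (adjusted p = 0.0101, adjusted p = 0.573 with an estimated correlation). Mitochondrial proteases had 0 higher and 10 lower of 20 (the same adjusted over the list alone), median -0.43 (adjusted p = 0.00326, adjusted p = 0.544 with an estimated correlation). Glycolysis targets had 0 higher and 11 lower of 25 (the same adjusted over the list alone), median -0.56 (adjusted p = 0.0101, adjusted p = 0.456 with an estimated correlation). Translocation had 9 higher and 4 lower of 32 (12 and 5 adjusted over the list alone), median 0.24 (adjusted p = 0.037, adjusted p = 0.528 with an estimated correlation). The p53 targets had 0 higher and 7 lower of 21 (0 and 8 adjusted over the list alone), median -0.49 (adjusted p = 0.0277, adjusted p = 0.58 with an estimated correlation). With quantile normalization the synthetases, mitochondrial proteases and glycolysis targets did not pass. In all 4195 genes were called, 1729 higher and 2466 lower. The share of higher calls was 41.2%, and 51.4% with normexp. Treated and untreated Atf4-null arrays lay on different slides of the run with the widest spread. Without untreated replicate 2 of Atf4-null cells 2418 genes were called. With array weights per run, chosen after seeing the data, 1041 were. With only the Atf4-null arrays in the limma fit 0 genes were called, against 2558 at an unadjusted p under 0.05.

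The Atf4-null response differed from the wild-type one in 4406 genes, 1577 with a higher and 2829 with a lower change. Lower changes were those of Cth (-5.49 ± 0.40), the glycoprotein hormone gene Stc2 (-4.87 ± 0.36), Slc7a11 (-3.82 ± 0.70), Derl3 (-6.84 ± 0.47) and the synthetase gene Eprs (-2.75 ± 0.40). Ddit3 differed by -1.20 ± 0.24. ISR signalling had 1 higher and 19 lower of 25 (the same adjusted over the list alone), median -1.81 (adjusted p = 4.91e-09). Amino acid synthesis had 0 higher and 16 lower of 19 (the same adjusted over the list alone), median -2.48 (adjusted p = 7.26e-12). Transporters had 0 higher and 10 lower of 16 (the same adjusted over the list alone), median -1.39 (adjusted p = 4.47e-05). With an estimated correlation these 3 calls held. The tRNA synthetases had 0 higher and 19 lower of 20 (the same adjusted over the list alone), median -1.62 (adjusted p = 7.26e-12, adjusted p = 0.0874 with an estimated correlation). Chaperones did not pass, with 1 higher and 5 lower of 26 (1 and 4 adjusted over the list alone), median -0.25 (adjusted p = 0.274). ER-associated degradation had 2 higher and 12 lower of 24 (2 and 13 adjusted over the list alone), median -0.52 (adjusted p = 0.00683, adjusted p = 0.212 with an estimated correlation), and -0.52 and -0.53 against runs 1 and 2. Translocation had 0 higher and 14 lower of 32 (0 and 15 adjusted over the list alone), median -0.43 (adjusted p = 0.000602, adjusted p = 0.212 with an estimated correlation), and -0.44 and -0.50 against the runs. Against wild-type runs 1 and 2 the medians were -1.93 and -1.73 for ISR signalling, -2.59 and -2.51 for synthesis and -1.59 and -1.50 for synthetases.

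Cholesterol genes also had lower changes in Atf4-null than in wild-type cells, with 1 higher and 18 lower of 24 (1 and 19 adjusted over the list alone), median -2.07 (adjusted p = 4.46e-06, adjusted p = 0.515 with an estimated correlation). Their medians were -2.85 and -1.17 against runs 1 and 2. Cell cycle genes had 0 higher and 21 lower of 29 (1 and 22 adjusted over the list alone), median -1.16 (adjusted p = 1.62e-08, adjusted p = 0.102 with an estimated correlation), with -1.06 and -1.19 against the runs. Mitochondrial proteases had 0 higher and 15 lower of 20 (the same adjusted over the list alone), median -0.98 (adjusted p = 1.17e-06, adjusted p = 0.217 with an estimated correlation), with -1.05 and -0.96 against the runs. Interferon-stimulated genes had 11 higher and 0 lower of 23 (12 and 0 adjusted over the list alone), median 2.34 (adjusted p = 1.6e-06, adjusted p = 0.515 with an estimated correlation), with 3.94 and 0.88 against the runs. Of the genes raised in wild type, 1475 of 3067 (48.1%) had a smaller and 41 a larger response in Atf4-null cells. Of those lowered, 939 of 2357 (39.8%) had a smaller and 157 a larger one. Among the smaller ones, 364 and 238 were called in the reverse direction. Against runs 1 and 2 alone 4206 and 4250 differed. The median of all genes lay at -0.13, and at -0.003 with quantile normalization, which moved the share of higher calls from 35.8% to 50.8%. Without untreated replicate 2 of Atf4-null cells 2574 genes differed.

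In eIF2α A/A cells, where eIF2α cannot be phosphorylated at the site PERK uses, tunicamycin raised the ER oxidoreductase Ero1b by 3.04 ± 0.26, Dnajb9 by 2.97 ± 0.14, Sdf2l1 by 2.59 ± 0.19 and Hspa5 by 1.60 ± 0.14 (n = 2 per group). Asns (-0.03 ± 0.25), Trib3 (-0.14 ± 0.29), Chac1 (0.88 ± 0.41) and Atf3 (-0.87 ± 0.41) did not pass (adjusted p = 0.984, 0.89, 0.273 and 0.282). Ddit3 rose by 1.13 ± 0.20, a call lost without untreated replicate 1. Fbln2 (-3.70 ± 0.32) and Ccn2 (-2.67 ± 0.39), both of the extracellular matrix, fell. Chaperones had 19 higher and 0 lower of 26 (24 and 0 adjusted over the list alone), median 1.19 (adjusted p = 2.63e-36). ER-associated degradation, with Selenos at 2.08 ± 0.14, had 10 higher and 0 lower of 24 (14 and 0 adjusted over the list alone), median 0.49 (adjusted p = 4.02e-13). Translocation had 16 higher and 0 lower of 32 (22 and 0 adjusted over the list alone), median 0.59 (adjusted p = 1.31e-17). With an estimated correlation these 3 calls held in eIF2α A/A cells. Autophagy genes had 4 higher and 0 lower of 25 (9 and 0 adjusted over the list alone), median 0.42 (adjusted p = 0.00025, adjusted p = 0.36 with an estimated correlation). Amino acid transporters, with Slc3a2 at 2.13 ± 0.21, had 3 higher and 1 lower of 16 (4 and 1 adjusted over the list alone), median 0.28 (adjusted p = 0.0295, adjusted p = 0.327 with an estimated correlation).

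Amino acid synthesis did not pass in eIF2α A/A cells, with 0 higher and 0 lower of 19 (the same adjusted over the list alone), median -0.03 (adjusted p = 0.388). Nor did tRNA synthetases, with 0 higher and 0 lower of 20 (the same adjusted over the list alone), median -0.15 (adjusted p = 0.141). ISR signalling, with the stress protein gene Ndrg1 at 1.67 ± 0.19, had 2 higher and 0 lower of 25 (3 and 1 adjusted over the list alone), median 0.38 (adjusted p = 0.0295, adjusted p = 0.0942 with an estimated correlation). With quantile normalization ISR signalling and transporters did not pass. In all 708 genes were called, 445 higher and 263 lower, and 347 with the replicate block. The count was 207 and 195 without untreated replicates 1 and 2, and 235 and 174 without treated replicates 1 and 2. The narrow spread of run 3 was pooled with the wider one of run 1, and with only these 4 arrays in the fit 3280 genes were called.

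Set against wild type, the eIF2α A/A response differed in 2634 genes, 1174 with a higher and 1460 with a lower change. Fgf21 (-6.74 ± 0.85), Slc7a11 (-5.40 ± 0.70), Atf3 (-4.32 ± 0.50), Cth (-3.60 ± 0.40) and Ddit3 (-3.54 ± 0.24) had lower changes. The vascular growth factor gene Angpt1 (6.59 ± 0.59) had a higher change. ISR signalling had 1 higher and 20 lower of 25 (the same adjusted over the list alone), median -1.61 (adjusted p = 1.94e-11). Amino acid synthesis had 0 higher and 16 lower of 19 (0 and 17 adjusted over the list alone), median -1.77 (adjusted p = 3.38e-12). Transporters had 0 higher and 9 lower of 16 (1 and 9 adjusted over the list alone), median -1.42 (adjusted p = 0.000271). Chaperones had 1 higher and 16 lower of 26 (1 and 17 adjusted over the list alone), median -0.74 (adjusted p = 8.84e-09). These 4 calls held with an estimated correlation. The tRNA synthetases had 0 higher and 15 lower of 20 (0 and 17 adjusted over the list alone), median -1.45 (adjusted p = 3.38e-12, adjusted p = 0.0639 with an estimated correlation). ER-associated degradation had 0 higher and 7 lower of 24 (0 and 9 adjusted over the list alone), median -0.40 (adjusted p = 0.000698, adjusted p = 0.103 with an estimated correlation). Translocation did not pass, with 1 higher and 1 lower of 32 (0 and 0 adjusted over the list alone), median -0.01 (adjusted p = 0.736).

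Medians of eIF2α A/A differences against wild-type runs 1 and 2 were -1.52 and -1.60 for ISR signalling, -2.01 and -1.90 for synthesis and -1.40 and -1.33 for transporters. They were -0.74 and -0.74 for chaperones and -0.27 and 1.37 for cholesterol genes. Of the genes raised in wild type, 1247 of 3067 (40.7%) responded less and 6 more in eIF2α A/A cells. Of those lowered, 977 of 2357 (41.5%) responded less and 5 more. The median eIF2α A/A change was 0.0636 of the wild-type change over the genes that rose at least 2-fold there, against 0.204 for Atf4-null cells. Against runs 1 and 2 alone 3031 and 2589 genes differed. The median of all genes lay at -0.06, and at 0.07 with quantile normalization, which moved the share of higher calls from 44.6% to 56.2%. Without untreated replicates 1 and 2 of eIF2α A/A cells the count was 1575 and 1446, and without treated replicates 1 and 2 it was 1575 and 1407.

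**Figure D2:**
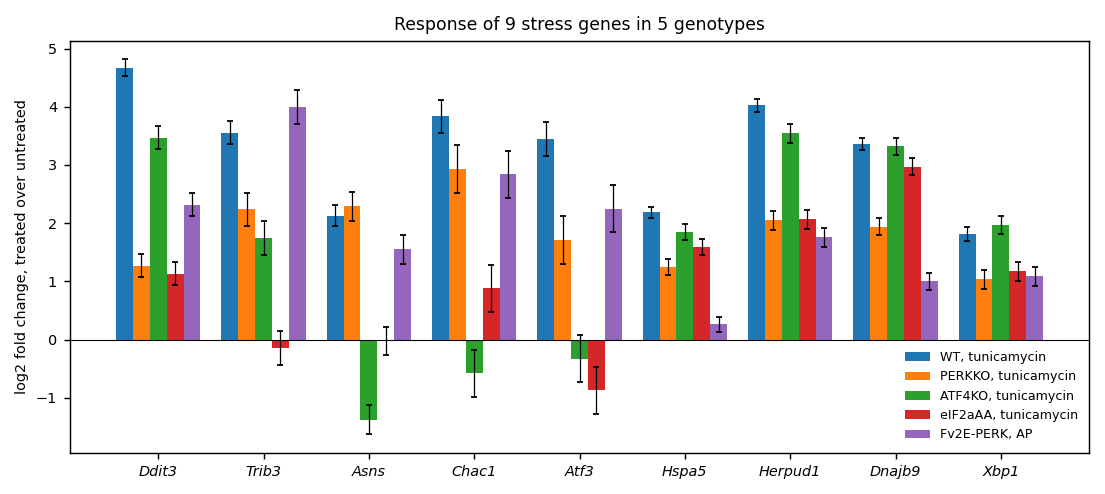
Log2 change of 9 known ER stress genes with treatment in the 5 genotypes, as bars with SE. Ddit3, Herpud1 and Dnajb9 pass the test in all 5 genotypes, and Asns passes as higher in wild-type, Perk-null and Fv2E-PERK cells and as lower in Atf4-null cells.

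Fv2E-PERK cells addressed what PERK signalling does without tunicamycin. AP raised Car6 at least 84.8-fold and Akr1b7 at least 19.1-fold (n = 2 per group). The cholesterol acyltransferase Soat2 rose by 6.17 ± 0.36, Cox6a2 of the respiratory chain by 5.33 ± 0.75 and the stress hormone Gdf15 by 4.21 ± 0.65. Trib3 rose 15.9-fold, Chac1 by 2.84 ± 0.41, Ddit3 by 2.32 ± 0.20, Herpud1 by 1.76 ± 0.16 and Asns by 1.55 ± 0.25. Dnajb9 went from -0.45 to 0.55 and Xbp1 from 4.11 to 5.19, while Hspa5 did not pass (0.26 ± 0.14, adjusted p = 0.362). Lox, an oxidase that crosslinks collagen, fell at least 8.85-fold, a call lost with normexp. ISR signalling had 12 higher and 0 lower of 25 (18 and 0 adjusted over the list alone), median 1.20 (adjusted p = 2.89e-19). Amino acid synthesis, with Cth at 2.13 ± 0.32, had 8 higher and 0 lower of 19 (9 and 0 adjusted over the list alone), median 0.73 (adjusted p = 1.28e-08). Fibroblast markers had 0 higher and 2 lower of 14 (0 and 3 adjusted over the list alone), median -0.43 (adjusted p = 9.03e-05). With an estimated correlation these 3 calls held.

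The other 14 list calls with AP did not hold so. The tRNA synthetases, with Tars at 1.29 ± 0.21, had 6 higher and 0 lower of 20 (12 and 0 adjusted over the list alone), median 0.64 (adjusted p = 1.05e-07, adjusted p = 0.146 with an estimated correlation). Transporters, with Slc6a9 at 2.15 ± 0.32, had 6 higher and 0 lower of 16 (8 and 0 adjusted over the list alone), median 0.52 (adjusted p = 0.000677, adjusted p = 0.0722 with an estimated correlation). Mitochondrial proteases, with Lonp1 at 0.99 ± 0.11, had 2 higher and 0 lower of 20 (3 and 0 adjusted over the list alone), median 0.24 (adjusted p = 0.00166, adjusted p = 0.337 with an estimated correlation). Matrix genes had 0 higher and 2 lower of 30 (0 and 7 adjusted over the list alone), median -0.53 (adjusted p = 2.82e-07, adjusted p = 0.269 with an estimated correlation). Cholesterol genes had 0 higher and 2 lower of 24 (the same adjusted over the list alone), median -0.73 (adjusted p = 1.28e-08, 0.269 with an estimated correlation). Epithelial markers had 0 higher and 1 lower of 11 (0 and 4 adjusted over the list alone), median -0.47 (adjusted p = 0.004, adjusted p = 0.0905 with an estimated correlation). Haematopoietic markers had 0 higher and 0 lower of 7 (the same adjusted over the list alone), median -0.37 (adjusted p = 0.0127, adjusted p = 0.0877 with an estimated correlation). Muscle markers had 0 higher and 1 lower of 8 (the same adjusted over the list alone), median -0.53 (adjusted p = 0.00526, adjusted p = 0.228 with an estimated correlation). Interferon-stimulated genes had 0 higher and 0 lower of 23 (the same adjusted over the list alone), median 1.04 (adjusted p = 0.00526, adjusted p = 0.585 with an estimated correlation). Glycolysis targets had 0 higher and 2 lower of 25 (the same adjusted over the list alone), median -0.29 (adjusted p = 6.65e-05, adjusted p = 0.146 with an estimated correlation). NRF2 genes had 0 higher and 1 lower of 22 (0 and 2 adjusted over the list alone), median -0.21 (adjusted p = 0.00253, adjusted p = 0.285 with an estimated correlation). Apoptosis regulators had 0 higher and 0 lower of 25 (the same adjusted over the list alone), median -0.17 (adjusted p = 0.00763, 0.189 with an estimated correlation). Inflammatory genes had 1 higher and 1 lower of 16 (the same adjusted over the list alone), median -0.58 (adjusted p = 0.0435, adjusted p = 0.58 with an estimated correlation). ER-associated degradation had 1 higher and 0 lower of 24 (3 and 0 adjusted over the list alone), median 0.16 (adjusted p = 0.023, adjusted p = 0.269 with an estimated correlation), and did not pass with quantile normalization. The chaperone list did not pass, with 2 higher and 0 lower of 26 (the same adjusted over the list alone), median 0.09 (adjusted p = 0.189), nor did translocation, with 1 higher and 0 lower of 32 (the same adjusted over the list alone), median 0.04 (adjusted p = 0.938). In all 588 genes were called with AP, 403 higher and 185 lower, and 281 with the replicate block. The count was 191 and 151 without untreated replicates 1 and 2, and 165 and 138 without AP replicates 1 and 2. With only these arrays in the fit, all of run 3 with its narrow spread, 4162 were called.

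**Figure D3:**
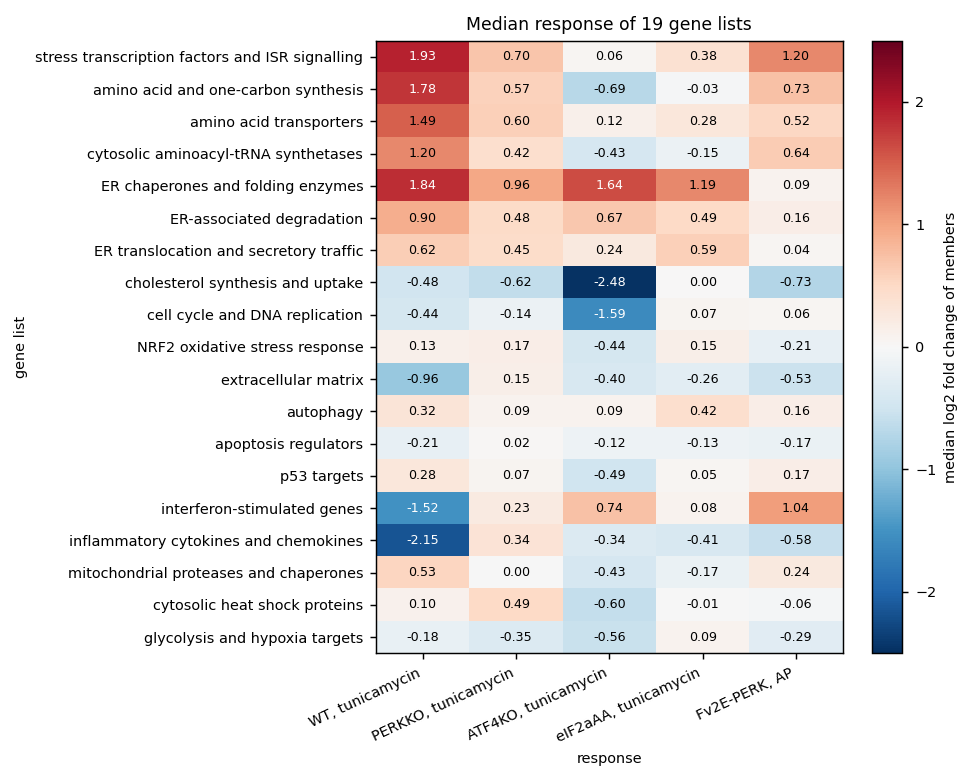
Median log2 change of 19 functional gene lists (rows) with treatment in the 5 genotypes (columns), shown as a colour scale. ER chaperones have medians of 1.84, 0.96, 1.64 and 1.19 with tunicamycin in wild-type, Perk-null, Atf4-null and eIF2α A/A cells and 0.09 with AP, and amino acid synthesis 1.78, 0.57, -0.69, -0.03 and 0.73.

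The responses were also set beside each other gene by gene. Of the genes raised in Perk-null, Atf4-null and eIF2α A/A cells, 185 of 271 (68.3%), 589 of 1729 (34.1%) and 230 of 445 (51.7%) also rose with tunicamycin in wild-type cells. Of the genes raised by AP in Fv2E-PERK cells 268 of 403 (66.5%) did. Independent lists would share 57.5, 367, 94.4 and 85.5 genes. Of the genes lowered, 28 of 59, 629 of 2466, 91 of 263 and 134 of 185 were also lower in wild type, against 9.62, 402, 42.9 and 30.2. None of these pairs of responses shares an array. Across all tested genes, which are not independent replicates, the 4 responses correlated with that of wild type at r of 0.11, 0.149, 0.0253 and 0.356.

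Genes that rose in wild-type cells and responded less in all 3 tunicamycin-treated mutants numbered 439, with a median wild-type change of 1.14. The 20 with the largest wild-type rise held Car6, Derl3, Acox2, Cox6a2, Soat2, Chchd10 and Ddit3. As the set was drawn from the 3067 raised genes, lists were set against these, a choice made after seeing the result. It held 11 of 20 raised ISR signalling genes, against 2.86 expected (Fisher's exact test, adjusted p = 0.000238), 11 of 16 synthesis genes (2.29, adjusted p = 2.14e-05) and 7 of 12 mitochondrial proteases and chaperones (1.72, adjusted p = 0.0034). The tRNA synthetases with 6 of 19 (2.72) and transporters with 4 of 10 (1.43) did not pass (adjusted p = 0.183 each). Nor did ER chaperones with 4 of 26 (3.72, adjusted p = 1) or degradation genes with 4 of 18 (2.58, adjusted p = 0.877). The mirror set, lower in wild type and less negative in all 3 mutants, numbered 350.

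AP raised 102 of the 439 genes (23.2%), against 38.4 expected from the 268 that it raised among the 3067 (Fisher's exact test, p = 1.78e-24), and lowered 0 of them by the limma test. The 102 had a median wild-type change of 1.97. Genes were not matched for the size of that change here either, so its part in the overlap was not tested. Soat2 (6.17 ± 0.36), Cox6a2 (5.33 ± 0.75) and Chchd10 (2.40 ± 0.30) were among the 102. Derl3 (-0.47 ± 0.38, adjusted p = 0.61) was not. The 102 included 7 ISR signalling genes, 6 synthesis genes, 3 transporters, 3 tRNA synthetases and 0 ER chaperones.

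The 3 mutant differences share the wild-type arrays. Simulated unchanged mutants against those arrays gave 0 genes of the 439-gene kind in 50 draws, and independent lists would give 4.02. Lower changes shared by Perk-null and Atf4-null cells numbered 537 (independent lists 188), by Perk-null and eIF2α A/A cells 639 (96.9) and by Atf4-null and eIF2α A/A cells 898 (286), each 0 when simulated. Mutants without an effect yield few calls by construction, so these values of 0 do not measure how far the shared arrays raise the overlap of real calls. With the wild-type arrays split between both mutants these counts were 355 (157), 448 (96.1) and 592 (240). Covariances of the differences were 0.553, 0.707 and 0.547, against 0.0816, 0.0809 and 0.0823 simulated. Against wild-type run 1 or run 2 alone the set numbered 599 and 387, with 325 and 273 of the 439 in it. It numbered 255 with the replicate block, and 253, 249 and 669 without Perk-null untreated replicate 1, Perk-null treated replicate 1 and Atf4-null untreated replicate 1. The set of 102 numbered 53 with the replicate block. It numbered 48 and 41 without Fv2E-PERK untreated replicates 1 and 2, and 44 and 41 without AP replicates 1 and 2.

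Untreated Perk-null and wild-type cells differed in 5945 genes in the fit with the run term, 2356 higher and 3589 lower in Perk-null cells. The matrix genes Smoc2, Postn and Mmp3 were at least 706-fold, at least 184-fold and at least 127-fold lower. Bounds of untreated comparisons used the wild-type arrays of the same run only (n = 2 per genotype). The homeobox genes Hoxd13 and Pitx1, which pattern the limb, were at least 193-fold and at least 152-fold lower. Wfdc2, a secreted protease inhibitor gene, was at least 655-fold higher. Matrix genes had 0 higher and 23 lower of 30 (0 and 24 adjusted over the list alone), median -2.26 (adjusted p = 2.92e-10, adjusted p = 0.203 with an estimated correlation). Fibroblast markers, with Twist2 at -3.91 ± 0.29 and Pdgfra at -3.03 ± 0.40, had 1 higher and 9 lower of 14 (1 and 10 adjusted over the list alone), median -1.21 (adjusted p = 0.00289, adjusted p = 0.0538 with an estimated correlation). Epithelial markers, with keratin Krt18 at 6.05 ± 0.39, had 6 higher and 0 lower of 11 (the same adjusted over the list alone), median 1.73 (adjusted p = 0.00032, adjusted p = 0.0538 with an estimated correlation). Haematopoietic markers, with Aif1 at least 7.64-fold higher, had 4 higher and 0 lower of 7 (the same adjusted over the list alone), median 1.40 (adjusted p = 0.00847, adjusted p = 0.0617 with an estimated correlation).

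Glycolysis and hypoxia targets, with Aldoc at 6.09 ± 0.15 and Car9 at 5.06 ± 0.57, had 16 higher and 1 lower of 25 (16 and 2 adjusted over the list alone), median 0.75 (adjusted p = 1.21e-06, adjusted p = 0.0873 with an estimated correlation) in untreated Perk-null cells. Chaperones had 0 higher and 16 lower of 26 (the same adjusted over the list alone), median -0.64 (adjusted p = 0.00032, adjusted p = 0.0538 with an estimated correlation). Translocation had 0 higher and 18 lower of 32 (the same adjusted over the list alone), median -0.48 (adjusted p = 0.000311, adjusted p = 0.17 with an estimated correlation). The tRNA synthetases had 0 higher and 13 lower of 20 (the same adjusted over the list alone), median -0.81 (adjusted p = 0.00032, adjusted p = 0.365 with an estimated correlation). Amino acid synthesis had 2 higher and 13 lower of 19 (2 and 14 adjusted over the list alone), median -0.79 (adjusted p = 0.00793, adjusted p = 0.343 with an estimated correlation). Trib3 (-2.29 ± 0.27) and Chac1 (-1.96 ± 0.38) were lower. No list call of this comparison held with an estimated correlation. Perk-null cells had Xist and no Y-linked signal and the wild-type cells of run 2 the reverse, although the file names give those as the wild type of the Perk line, so genotype and origin of the cells cannot be told apart.

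Untreated Atf4-null and wild-type cells differed in 3048 genes in the same fit, 1506 higher and 1542 lower. Trib3 (-3.12 ± 0.27), the folate enzyme Aldh1l2 (-4.24 ± 0.66), Asns (-2.14 ± 0.23) and the synthetase gene Cars (-1.62 ± 0.17) were lower in Atf4-null cells. Myh1 and Myh8 were at least 38.4-fold and at least 41.7-fold higher (n = 2 per genotype, run 1). The antiviral genes Rsad2 (-5.55 ± 0.57) and Xaf1 (-7.86 ± 1.11) were lower, and Krt18 at least 24.2-fold lower. ISR signalling had 0 higher and 11 lower of 25 (the same adjusted over the list alone), median -0.67 (adjusted p = 5.12e-06), the only list call of this comparison that held with an estimated correlation. Genes of amino acid synthesis had 1 higher and 10 lower of 19 (1 and 14 adjusted over the list alone), median -0.75 (adjusted p = 1.45e-05, adjusted p = 0.188 with an estimated correlation). Interferon-stimulated genes had 0 higher and 17 lower of 23 (0 and 20 adjusted over the list alone), median -2.79 (adjusted p = 5.76e-09, adjusted p = 0.647 with an estimated correlation). Inflammatory genes had 0 higher and 5 lower of 16 (1 and 7 adjusted over the list alone), median -1.18 (adjusted p = 0.00256, adjusted p = 0.822 with an estimated correlation). Glycolysis and hypoxia targets had 1 higher and 18 lower of 25 (2 and 18 adjusted over the list alone), median -0.69 (adjusted p = 3.73e-07, adjusted p = 0.178 with an estimated correlation). Cholesterol genes had 6 higher and 1 lower of 24 (7 and 1 adjusted over the list alone), median 0.88 (adjusted p = 0.000695, adjusted p = 0.822 with an estimated correlation).

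Further list calls, none kept with an estimated correlation, are named without their values. In eIF2α A/A cells they were NRF2, matrix, inflammatory and mitochondrial genes. For Perk-null differences from wild type they were cell cycle, inflammatory, mitochondrial, heat shock and muscle genes. For Atf4-null differences they were matrix, p53, inflammatory, heat shock and haematopoietic genes, and for eIF2α A/A differences cholesterol, cell cycle, matrix, interferon, mitochondrial, glycolysis and fibroblast genes. In untreated Perk-null cells they were degradation, mitochondrial and heat shock genes, and in untreated Atf4-null cells the tRNA synthetases.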

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

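The test of a wider spread in run 1 and the test on homeobox genes were chosen only after the result was seen, and so were the limits by which the test on wild-type RNA was read as open. The other tests were chosen before their results were seen.

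Of 28 groups of 4 wild-type values examined for a sample far from the others, 3 held one, and chance gives about 1 in 20. Xbp1 read 4.587 on the array of untreated wild-type replicate 1 and 4.213 to 4.25 on the other 3. Hspa5 read 9.23 on treated wild-type replicate 1 and 9.046 to 9.075 on the others. Untreated wild-type replicate 2 had 45.1% of probes well above background, against 55.66% to 56.94% on the others. All 3 arrays belong to run 1, the run with the widest spread.

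Genes whose response to tunicamycin went in opposite directions in wild type and a mutant, with both responses and their difference past the test, were counted. They numbered 35 for Perk-null cells, of which 11 rose in wild type and 24 fell there, against 12.5 and 44.2 for independent lists. Cxcl10 was among them, which rose in Perk-null and fell in wild-type cells. For Atf4-null cells there were 602 such genes, of which 364 rose in wild type and fell in Atf4-null cells (523 for independent lists) and 238 did the reverse (282), among the 364 them Asns, Psat1, Cth and the synthetase genes Cars, Gars and Lars. For eIF2α A/A cells there were 145, of which 65 rose in wild type and 80 fell there, against 55.8 and 72.6. The Perk-null and Atf4-null counts thus lay below those of independent lists.

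Probes that matched no gene name were outside every comparison of named genes. Of 14025 such probes past the background filter, 1672 were called in the wild-type response, 930 higher and 742 lower, and 119 were called with AP, 69 higher and 50 lower.

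The first pattern weighed was the large number of genes called in Atf4-null cells with tunicamycin, 4195 with 2 arrays per group. A slide effect would be shared with the wild-type arrays of run 1, since treated and untreated arrays of both genotypes lay on the same 2 slides. Across genes, however, the Atf4-null response had r of -0.008458 with the wild-type response of run 1 minus that of run 2, which argues against a slide effect common to both genotypes. The dimmest array was not decisive, since 2965 genes were called without treated replicate 1 and 3359 without treated replicate 2. A spread in run 1 wider than the pooled estimate also stays open for part of the count: with array weights per run 1041 genes were called.

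The second pattern was the Atf4 signal of 2.79 on Atf4-null untreated replicate 1, against -0.05, -4.27 and 0.01 on the other Atf4-null arrays. It amounted to 4.235% of the untreated wild-type signal, and to 3.188% at a second Atf4 probe. If wild-type RNA had entered this sample, 18 genes absent from the other Atf4-null arrays should have shown a like share, and their median share was -0.2176% (quartiles -0.549% and 0.7915%). That value met the bound set in advance against the explanation, but the bound was wrong for these genes: at such a share only 1 of the 18 would reach 4 times the highest background floor, and 5 were asked for. That gene, Nos2, had a share of -0.367% and was not well above background, and the next brightest, Oas3, had 0.0876%. The dim genes Iigp1 and Eml2 had shares at or above that of Atf4, and 5 of the 18 were well above background. With 1 gene bright enough, wild-type RNA cannot be told apart from a signal of the targeted gene itself.

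The third pattern was a set of homeobox genes, such as Hoxd13, among the differences between untreated Perk-null and wild-type cells. Of 36 Hox genes tested 19 differed, 7 higher and 12 lower, which is 52.8% against 41.1% of other genes (Fisher's exact test, one-sided, p = 0.106, adjusted p = 0.528). In untreated Atf4-null cells 19 of 36 differed as well, 14 higher and 5 lower, against 21% of other genes (Fisher's exact test, p = 2.74e-05, adjusted p = 0.000274). An origin of the lines from different parts of the embryo may contribute. It cannot be told apart from the genotype, as the labels name no line and no mutant is known from more than 1. By file name the wild types of runs 1 and 2 are of the Atf4 and the Perk line. Hoxc9 differed between them untreated (-2.81 and -7.07), and Hoxd13 little (3.23 and 3.36).

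Of the 35 splits of the 8 wild-type arrays into 4 and 4, only the real one, fitted with a run term, gave 5424 genes. The others mix both treatments, which can lower their counts, so chance was not excluded. The highest other value, 5104, came from the split that follows the scan run, fitted without a run term. Without that term the real split gave 3603, fewer than the split by run, so that the rank of the real split rests on that term. This points to a structure of the samples by run, and the wild-type cells of both runs also differed in Xist and Y-linked genes. The next highest split gave 123. Within run 1 and run 2 alone, 4697 and 3760 genes were called.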

How the results depend on the processing

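The slide 3 term, the crossed Perk-null block and the array weights were chosen only after the result was seen. Signal over background limits dim genes, and folds against dim groups are lower bounds. The 12 counts of the report stayed within 1.5 times under quantile normalization, normexp, the deposited values, the filter on all 24 arrays, the mean of a gene's probes, and trend and robust settings. With the wild-type arrays of 1 run alone the untreated comparison of the mutant in the other run could not be fitted. The counts that moved further follow, and the cause was not tested except where given.

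Without a run term the counts were 3603 for the wild-type response, 113 for Perk-null, 2422 for Atf4-null and 234 for eIF2α A/A cells and 185 for AP. The differences from wild type numbered 769, 2401 and 1254 for Perk-null, Atf4-null and eIF2α A/A cells, and untreated Atf4-null cells gave 1040. The 3-mutant set held 182 genes, 41 of them raised by AP. With slide as a random block the wild-type response gave 3365, Atf4-null 2278, the Perk-null difference 1167 and the set 278. With scan day as a random block Perk-null cells gave 994, eIF2α A/A 2018, AP 1560 and the set with AP 183. With the wild-type arrays of run 2 alone the counts were 884, 1516 and 1403 for Perk-null, eIF2α A/A and AP, a fit that leaves out wild-type arrays of the run with the widest spread. No filter on dim probes gave 214 for Perk-null cells, 368 for AP and 67 for the set with AP.

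The replicate block gave 153 for Perk-null, 347 for eIF2α A/A, 281 for AP, 1177 for the Perk-null difference, 255 for the set and 53 with AP, and changed no other count by over 1.5 times. Residuals of Perk-null arrays followed the slide across replicate numbers, and with those numbers crossed the response gave 157 and the difference 1244. With only the groups compared in the limma fit, Perk-null and Atf4-null responses gave 0 and 0. That fit gave 3280 for eIF2α A/A, 4162 for AP, 1113 and 1643 for the Perk-null and Atf4-null differences, 1080 for untreated Atf4-null cells and 214 for the set. With array weights per run the counts were 1627, 1041, 5660 and 5580 for the Perk-null, Atf4-null, eIF2α A/A and AP responses. They were 3233, 1421 and 5545 for the 3 differences, 1064 for untreated Atf4-null cells and 274 for the set with AP. These weights were 0.2572, 1.334 and 2.915 for runs 1 to 3.

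At an adjusted p under 0.01 the counts were 134, 2277, 249 and 202 for the Perk-null, Atf4-null, eIF2α A/A and AP responses, and 802, 2305 and 1291 for the differences. Untreated Atf4-null cells gave 1757, the set 167 and the set with AP 43. At least 2-fold changes numbered 1861, 151, 1921, 355 and 304 for wild-type, Perk-null, Atf4-null, eIF2α A/A and AP responses, and 1192, 2627 and 1688 for the differences. They numbered 2995 and 1739 for untreated Perk-null and Atf4-null cells, 187 for the set and 53 with AP. Both settings are stricter by construction.

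Leaving out 1 array gave 4705 to 5070 for wild type, 103 to 206 for Perk-null, 2418 to 5424 for Atf4-null, 174 to 235 for eIF2α A/A and 138 to 191 for AP. The differences ranged from 981 to 1985, 2574 to 5844 and 1407 to 2778. Untreated Perk-null and Atf4-null cells ranged from 4253 to 6121 and from 2383 to 3777, the set from 249 to 669 and the set with AP from 41 to 148. Any of a genotype's own 4 arrays moved the Perk-null, eIF2α A/A and AP responses by over 1.5 times. The same held for the Perk-null and eIF2α A/A differences and the set with AP (counts above). Atf4-null untreated replicate 2 moved that response and its difference. Perk-null untreated and treated replicate 1 and Atf4-null untreated replicate 1 moved the set. A group left with 1 array was assumed to vary like the other groups.

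Of the 884 values of named genes, called or not, 815 kept direction and side of the threshold with quantile normalization, 773 with normexp, 883 with the deposited values, 839 with the mean of probes, 812 without the filter, 627 without a run term, 739 with the replicate block and 585 with only the groups compared. With 1 array left out at a time 5664 values did, 786 lost their call, 14 gained one and 34 moved. Reversed values were few. With the wild-type arrays of run 2 alone Lum was at 0.51 and Map2 at -0.24 in the wild-type response. In untreated Perk-null cells Rsad2 was at -0.20 with normexp, and Dnajb11 at 0.10 with the mean of probes. Without a run term Rsad2 was there at -1.86, Ifih1 at -0.93 and Ccl5 at -0.44. With the replicate block Xist was at -1.68, Rsad2 at -5.54, Ifih1 at -2.82, Ccl5 at -2.27 and Vwf at -0.48. By construction the fit without a run term compared Perk-null cells with the wild-type arrays of both runs, and the replicate block with those of run 1. Of the 127 list calls 32 held and 95 were lost with an estimated correlation. With fry 26 were lost and 22 gained, with quantile normalization 14 and 7, and without a run term 7 and 3.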
